A study of Homo sapiens with 15 samples.

How the data were processed

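RNA from primary human endothelial cells was measured on 15 arrays of 2 channels each. Per the labels, channel 1 held untreated control cells and channel 2 held cells of the same endothelial type treated with interferon gamma (IFNg), tumour necrosis factor alpha (TNFa) or interleukin 4 (IL4). Each of the 3 cytokines had 5 arrays, 1 for each of 5 cell sources: lung, aortic, iliac, dermal and colon endothelial cells. Groups were taken from the array titles. For the IL4 lung array the title, the description and the control channel named lung cells, while the channel 2 source named iliac cells. It was kept as lung, and the differences of TNFa and IFNg from IL4 and the differences between cell sources were also run without it. The difference between vessel and organ cells under IL4 was not run without it. Doses, treatment times and the number of donors or cultures are not given in the sources used here.

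The deposited table held 1 value per probe and array for 37331 probes, with 0 missing values, and the authors' processing steps are not given in the sources used here. The unit was worked out from the values. Of 30000 values tested, 97% were, read as a log10, the log of a ratio of whole numbers up to 10000, against 2.433% read as a log2 and 3.4% read as a natural log. The deposited values were therefore taken as log10 ratios, and were converted to log2. The whole numbers behind a ratio, recovered as its smallest fraction, were used as a rough measure of brightness; their medians per array ran from 349 to 923 for the numerator and from 338 to 1063 for the denominator. Array medians over genes ran from -0.33 to 0.035 on the log2 scale, so neither dye nor array normalization was visible. Per the labels, the treated cells were in channel 2, but the dyes are not given in the sources used here. The direction, treated over control, is the likely one, because the interferon and NF-kB target genes named in the report were high under the cytokine known to induce them. All 15 arrays had the same channel order in the labels, and whether dyes were swapped is not given in the sources used here. If the dyes were not swapped, a dye effect of a single gene is part of each test of a cytokine against control and drops out of a difference between cytokines.

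Probes were named from GEO's platform annotation. Exactly 1 gene was named by 26940 probes, several genes by 333 and none by 10058, which are unnamed here rather than without a gene. Symbols were checked against a RefSeq gene table by Entrez number, which matched 26810 of the 26940 probes, and the other 130 kept the annotation's symbol. A gene's value was the mean of its probes that name it alone. This gave 11936 genes, of which 4506 had 1 probe and 7430 had several, up to 30. Genome coordinates were not used here. Probes of a gene disagreed in places, and the report gives the range of probe means for several of the genes concerned.

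Tests were made in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, two-sided, Benjamini-Hochberg over the 11936 genes, threshold 0.05). Each cytokine was tested as the mean log2 ratio of its 5 arrays against 0. Differences between cytokines came from 1 fit of all 15 arrays with cytokine and cell source as terms, and differences between cell sources from the F test of the same fit. Aortic and iliac arrays, which name a vessel, were set against lung, dermal and colon arrays within each cytokine. The replicates are cell sources, 1 array each, so adjusted p-values measure the spread between these arrays, part of which may be technical, and the number of arrays limits the precision. Before the data were examined, the design, the gene lists and the rule for named genes were fixed, on the assumption that the deposited values had been normalized. The values proved not to be centred, so the number of genes called in each comparison is also given with each array centred on its median. Counts with arrays left out are of deposited values unless stated. Gene values in the report are centred, and "rose" and "fell" are written only of genes called with the same sign in both deposited and centred values. A loess correction of each array on the recovered whole numbers (span 0.3), chosen after seeing the data, was run beside both.

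The named genes were, for each cytokine, the 10 highest and 10 lowest mean ratios among genes past the threshold with 1 sign on all 5 arrays, up to 4 called members of each list (or 2 members as values), and the anchors IRF1, CXCL10 and GBP1 (IFNg), SELE, VCAM1 and ICAM1 (TNFa), and CCL26 and VCAM1 (IL4). For each pair of cytokines they were the 8 largest differences each way, and for cell sources the 8 largest F. The pathway lists covered IFN-gamma signalling and guanylate-binding proteins, interferon-stimulated antiviral genes, MHC class I, MHC class II, NF-kB feedback, leukocyte adhesion, chemokines, cytokines and growth factors, the IL-4/STAT6 response, coagulation, vascular tone, angiogenesis, extracellular matrix, cell cycle, cell death, complement, cholesterol synthesis, redox and metal response, and housekeeping. The marker lists covered endothelial, lymphatic endothelial, leukocyte, fibroblast, smooth muscle and pericyte, and epithelial cells. Lists were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of 1 kind within a cytokine, and members were also counted when adjusted over the list alone. Limma's fry, also planned, asks whether the members depart from 0 rather than from the other genes. A list is said to pass on camera unless fry is named. List members that no probe names alone were not analysed here.

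Cell sources pair the arrays across cytokines, since the labels name the same endothelial type. The deviations of arrays from their cytokine's mean correlated across genes for each of the 15 pairs of 1 source (r from 0.101 to 0.705), and a cell source block was part of each fit that compares cytokines. Arrays of 1 source may share control RNA, so correlations and overlaps between cytokines were set beside simulated unchanged arrays with shared controls and beside pairs of cytokines taken from different sources. Each fit was tested on simulated data with known changes. The noise was drawn independently per gene and array with the spread of centred values, without array offsets, intensity trends or correlation between genes. The rates therefore describe that setting and not the deposited values. Among changed genes, a log2 change of 1 was recovered for 92.5% under IFNg, 95.5% under TNFa and 95.5% under IL4, for 97%, 98.5% and 100% in the TNFa minus IFNg, TNFa minus IL4 and IFNg minus IL4 differences, and for 89.6% between cell sources. Between vessel and organ cells a log2 change of 1 was recovered for 35.8% under IFNg, 52.2% under TNFa and 55.2% under IL4, a change of 2 for 83.3%, 80.3% and 97%, and a change of 0.5 for 2.99%, 2.99% and 0%. Alternatives were centring, centring with scaling, single probes, a filter on low ratios, robust variance, all arrays in 1 fit, a random cell source block, leaving out each array, a minimum size of change, and the loess values. Figures and tables were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.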

Results

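The study asked which genes inflammatory cytokines regulate in primary endothelial cells, the cells that line blood vessels, from 5 sites of the body. Treated cells were compared with untreated cells of the same source on each array, for IFNg (a lymphocyte cytokine), TNFa (which signals through NF-kB) and IL4 (which signals through STAT6). Each cytokine had 5 arrays, and 11936 genes were tested. Per gene, the value is the log2 ratio of treated over control, the likely direction, given relative to the median of its array as a mean ± SD over 5 cell sources. Before centring, the median gene lay at -0.19 under IFNg, -0.13 under TNFa and -0.12 under IL4, so changes are stated relative to that shift. The labels give no dyes, so a gene-specific dye effect cannot be separated from a ratio against control.

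**Figure D1:**
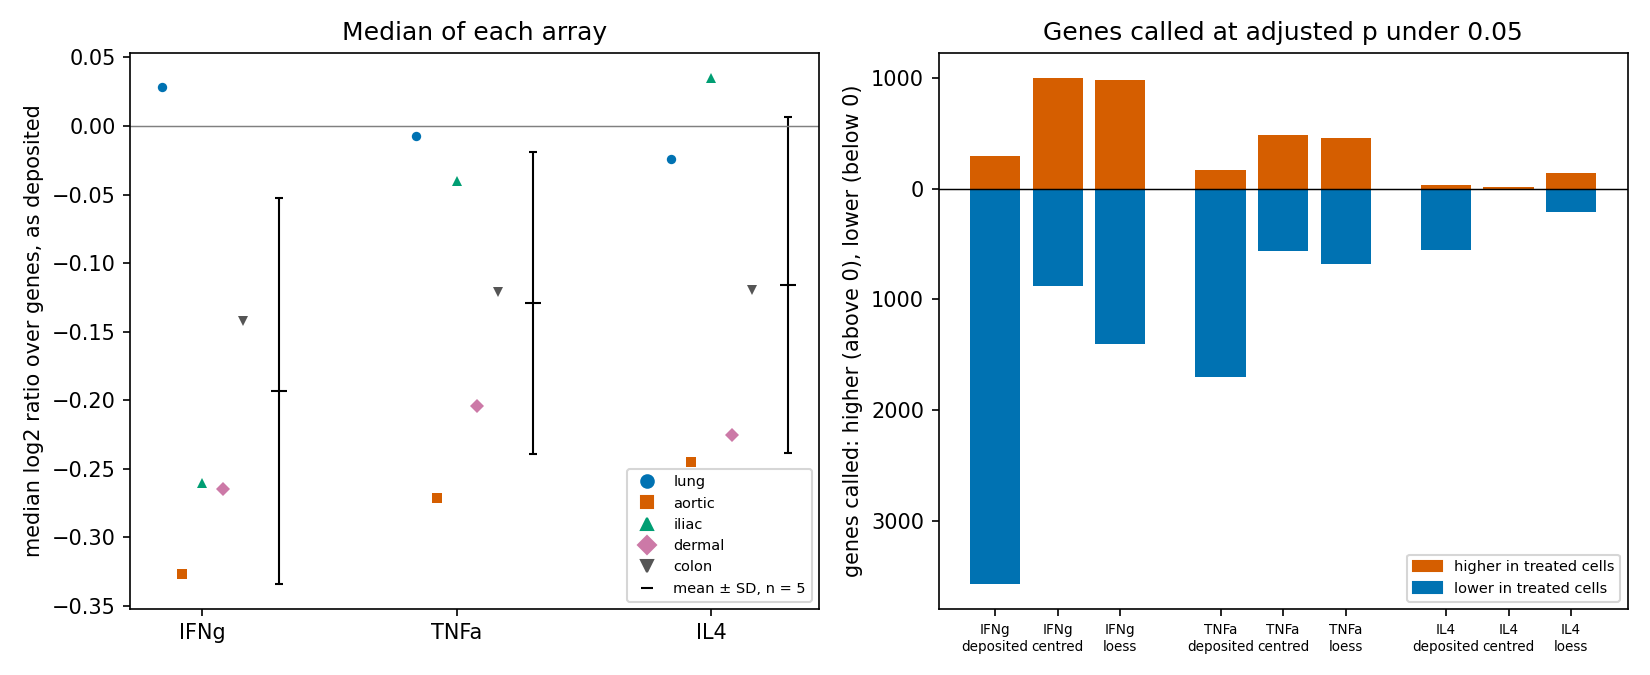
Left, the median log2 ratio of each array over genes as deposited, with the mean ± SD of the 5 arrays of each cytokine, running from -0.33 to 0.035. Right, the number of genes called higher (above 0) and lower (below 0) in treated cells with deposited, centred and loess values; under IFNg 291 genes were higher and 3568 lower as deposited, against 996 and 881 after centring.

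IFNg gave the largest ratios of the series. The chemokines CXCL9 (5.30 ± 0.36, 39.3-fold, n = 5), CXCL11 (4.70 ± 0.58, 25.9-fold) and CXCL10 (3.43 ± 0.75, 10.8-fold), which attract activated T cells, rose in cells of all 5 sources. IDO1, which breaks down tryptophan, rose 33.4-fold (5.06 ± 0.56), and WARS1, the tryptophanyl-tRNA synthetase, rose 9.98-fold (3.32 ± 0.32). The guanylate-binding protein GBP1 rose 13.1-fold (3.71 ± 0.38) and GBP3 7.13-fold (2.83 ± 0.21), although 1 of the 3 GBP3 probes alone gave -0.30 in deposited values. The complement protease C1S (2.80 ± 0.82), the antiviral gene SAMD9L (2.65 ± 0.13) and HLA-DPA1 (2.61 ± 0.93), an MHC class II chain, completed the 10 highest. The largest adjusted p of limma among these 10 genes was 0.00497 in deposited values and 0.00217 after centring. The decreases were smaller: HHIP, an antagonist of Hedgehog ligands, fell by 1.08 ± 0.50 (log2), the protease PRSS23 by 1.06 ± 0.36, the decoy receptor TNFRSF10D by 1.05 ± 0.61, the respiratory chain subunit UQCR10 by 1.04 ± 0.05 and the endothelial proteoglycan ESM1 by 1.03 ± 0.38. Each of these genes kept its call with any 1 array left out. In deposited values 3859 genes were called under IFNg, 291 higher and 3568 lower. After centring 1877 were called, 996 higher and 881 lower. In both, 291 were higher and 881 lower. After centring 59 of the called genes were at least 2-fold higher and 7 at least 2-fold lower. The deposited count changed with 1 array left out, being 7733 without lung, 872 without aortic, 1174 without iliac, 862 without dermal and 2216 without colon. Fewer arrays also lower the power, which was not separated from the influence of an array.

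The interferon lists moved together under IFNg. Of 35 measured antiviral genes 18 rose and 1 fell; with centred values 28 and 1 were called over all genes and 32 and 1 adjusted over the list alone. Among them SAMHD1, which depletes nucleotides in infected cells, rose by 2.27 ± 0.42, BST2 (tetherin) by 1.90 ± 0.45 and the RNA sensor IFIH1 by 1.73 ± 0.33. Of 22 genes of IFN-gamma signalling and GBPs 11 rose and 2 fell (14 and 2 over all genes with centred values, 17 and 2 adjusted over the list alone). The anchor IRF1, a transcription factor induced by interferon, was at 0.31 ± 0.10, with means of its 3 probes from -0.20 to 1.19. It was called after centring but not as deposited (limma adjusted p = 0.0189 and 0.234). Of 14 MHC class I genes 9 rose and 0 fell (10 and 0 over all genes with centred values, 12 and 1 adjusted over the list alone), with HLA-C at 1.77 ± 0.19, HLA-B at 1.75 ± 0.12 and HLA-E at 1.67 ± 0.19. Of 12 MHC class II genes 9 rose and 0 fell (12 and 0 over all genes with centred values, 12 and 0 adjusted over the list alone), among them HLA-DMA (1.60 ± 0.47) and the invariant chain CD74 (1.14 ± 0.20), with probe means from 0.48 to 2.69 and from 0.31 to 2.13. Of 22 cell death genes 11 rose and 0 fell (13 and 0, then 13 and 1 adjusted over the list alone), led by the apolipoproteins L APOL3 (2.52 ± 0.30) and APOL1 (2.48 ± 0.34) and by TNFSF10, the death ligand TRAIL (1.34 ± 0.23). In the camera test of centred values the adjusted p was 9.17e-20 for antiviral genes, 1.93e-10 for IFN-gamma signalling, 5.49e-09 for MHC class I, 3.05e-11 for MHC class II and 4.84e-07 for cell death. With an estimated correlation it was an adjusted p = 0.0323 for the antiviral and the IFN-gamma signalling lists, 0.0474 for cell death and 0.0749 for both MHC lists, and with deposited values none of the 5 passed (smallest adjusted p = 0.0856 with an estimated correlation). Without the lung array, the 3 calls with an estimated correlation were lost (adjusted p = 0.114 each), while the preset-correlation calls held and the list means moved little, from 1.05 to 1.01 for IFN-gamma signalling, from 0.69 to 0.67 for antiviral genes and from 0.58 to 0.59 for cell death.

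The other lists under IFNg held scattered calls. Of 35 cell cycle genes 0 rose and 6 fell (0 and 6 over all genes with centred values, 0 and 9 adjusted over the list alone), with TPX2, a spindle assembly factor, at -0.70 ± 0.36 and the kinetochore gene CENPF at -0.54 ± 0.34. The list was lower (adjusted p = 0.00796), but at adjusted p = 0.504 with an estimated correlation. Without the lung array its adjusted p was 0.117 and its mean -0.098, against -0.15. Of 29 chemokines 4 rose and 3 fell (8 and 3, then 10 and 4 adjusted over the list alone; adjusted p = 0.0589, against 0.00122 as deposited, or 0.289 as deposited with an estimated correlation). Of 24 cytokines and growth factors 2 rose and 3 fell (8 and 3, then 9 and 4 adjusted over the list alone; adjusted p = 0.264, against 0.0471 as deposited), with TGFB2 at -0.53 ± 0.16. Of 26 IL-4/STAT6 genes 3 rose and 2 fell (6 and 2, then 8 and 3 adjusted over the list alone; adjusted p = 0.0905, against 0.00799 as deposited); with an estimated correlation the adjusted p as deposited was 0.821 for the cytokine list and 0.501 for the IL-4/STAT6 list. The remaining lists did not pass camera. NF-kB feedback had 3 of 27 genes higher and 1 lower (5 and 1 adjusted over the list alone). With fry after centring it passed (adjusted p = 0.0295), as did chemokines (1.2e-04) and IL-4/STAT6 (0.0295), all higher. Cell cycle did not pass fry (0.107). Leukocyte adhesion had 2 of 17 higher and 3 lower (4 and 7 adjusted over the list alone), with a mean of 0.016, a median of -0.049 and a test direction of lower. Coagulation had 4 of 20 lower, including VWF, the platelet-binding von Willebrand factor (-0.86 ± 0.49), and ANXA2 (5 and 4 adjusted over the list alone). Vascular tone had 1 of 20 higher and 2 lower (3 and 2 adjusted over the list alone), with the peptide APLN at -0.80 ± 0.34. Angiogenesis had 4 of 25 lower (3 and 9 adjusted over the list alone), extracellular matrix 3 of 37 lower (6 and 9 adjusted over the list alone) and cholesterol synthesis 3 of 16 lower (0 and 3 adjusted over the list alone), the last including FDPS (-0.52 ± 0.24). Complement had 2 of 15 higher, C1S and its inhibitor SERPING1 (1.49 ± 0.70), and 1 lower (2 and 1 adjusted over the list alone). Redox and metal response had 2 of 20 higher and 3 lower (3 and 4 adjusted over the list alone), with the peroxidase PRDX1 at -0.76 ± 0.24. Of 13 housekeeping genes 2 fell, RPS18 (-0.66 ± 0.25) and GAPDH (-0.38 ± 0.14; probe means from -1.29 to 0.023), and 0 rose (0 and 2 adjusted over the list alone).

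The highest genes under TNFa included an adhesion molecule and several chemokines. ICAM1, which binds leukocyte integrins, rose 7.65-fold (2.93 ± 0.48, n = 5), the monocyte chemokine CCL2 7.04-fold (2.82 ± 0.68) and the membrane-bound chemokine CX3CL1 6.33-fold (2.66 ± 0.65). TLR2, a receptor for bacterial lipoproteins (2.29 ± 0.78), CCL7 (2.26 ± 0.75), the mitochondrial superoxide dismutase SOD2 (2.24 ± 0.41), the ubiquitin-like protein UBD (2.07 ± 0.76), CXCL6 (2.04 ± 0.996) and C1S (2.03 ± 0.80) rose by about 4-fold or more. VCAM1, an adhesion molecule for lymphocytes and monocytes, rose 3.90-fold (1.96 ± 0.21). Probes of 1 gene differed in size, with means from 1.63 to 4.22 for ICAM1, 0.18 to 3.91 for SOD2 and 0.32 to 3.50 for VCAM1. SELE, E-selectin, was at 0.65 ± 0.35; its call (adjusted p = 0.0202) was lost without the aortic or the colon array, where its deposited mean was 0.45 and 0.43. Among called genes with 1 sign on all 5 arrays, the 10 lowest ratios belonged to genes of varied function. MMRN1, a multimerin stored in endothelial cells, fell by 1.83 ± 0.46 (log2), the matrix protein EFEMP1 by 1.55 ± 0.50, the G-protein regulator RGS4 by 1.53 ± 0.80 and the co-chaperone DNAJB4 by 1.46 ± 0.52. The laminin receptor subunit ITGA6 fell by 1.45 ± 0.48, PALMD by 1.44 ± 0.40, the basement membrane netrin NTN4 by 1.41 ± 0.50, LDB2 by 1.32 ± 0.47, VWF by 1.29 ± 0.29 and KDR, the VEGF receptor, by 1.22 ± 0.59. All of these but SELE kept their calls with any 1 array left out, and their largest adjusted p of limma after centring was 0.0131. ALDH1A1 was not ranked, because its sign differed in colon cells. It was at -2.83 in lung, -3.00 in aortic, -3.471 in iliac, -3.475 in dermal and 0.20 in colon cells. In deposited values 1870 genes were called under TNFa, 164 higher and 1706 lower. After centring 1046 were called, 486 higher and 560 lower. In both, 164 were higher and 560 lower. The deposited count was 550 without aortic, 429 without dermal and 444 without colon.

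Several lists were higher under TNFa. Of 29 chemokines 12 rose and 0 fell (13 and 0 over all genes with centred values, 17 and 0 adjusted over the list alone). Of 27 NF-kB feedback genes 9 rose and 1 fell (16 and 1 over all genes with centred values, 21 and 1 adjusted over the list alone), among them TNFAIP3, the deubiquitinase A20 (1.71 ± 0.40), NFKBIA, the inhibitor IkB-alpha (1.29 ± 0.46), and TNIP1 (1.12 ± 0.36). Of 35 antiviral genes 9 rose and 1 fell (18 and 1, then 30 and 1 adjusted over the list alone). The list mean was 1.27 on the iliac array and 0.24 to 0.63 on the others. Without the iliac array it was 0.41 (camera adjusted p = 3.39e-12, or adjusted p = 0.283 with an estimated correlation). IFIH1, whose values ran from 0.99 on the aortic to 4.40 on the iliac array, was not called without the dermal or the colon array, where its deposited mean was 2.07 and 2.06. Of 14 MHC class I genes 4 rose and 0 fell (6 and 0, then 11 and 0 adjusted over the list alone), with HLA-C at 1.38 ± 0.47 and HLA-B at 1.29 ± 0.38. Of 22 IFN-gamma signalling genes 3 rose and 1 fell (3 and 1, then 4 and 1 adjusted over the list alone). Of 24 cytokines and growth factors 3 rose and 1 fell (7 and 1, then 8 and 1 adjusted over the list alone), with IL32 at 1.18 ± 0.47 and the macrophage factor CSF1 at 1.04 ± 0.25. Of 22 cell death genes 6 rose and 0 fell (7 and 0, then 9 and 1 adjusted over the list alone). The median of the cell death list was 0.19, and 0.065 without the iliac array (mean 0.29 and 0.21). Its camera adjusted p without that array was 0.00482, or 0.309 with an estimated correlation. In the camera test of centred values the adjusted p was 4.11e-08 for chemokines, 3.65e-12 for NF-kB feedback, 2.51e-13 for antiviral genes, 9.52e-07 for MHC class I, 7.47e-05 for IFN-gamma signalling, 0.00359 for cytokines and 0.00102 for cell death. With an estimated correlation none of these passed, with adjusted p = 0.131 for chemokines, 0.143 for NF-kB feedback and MHC class I, and 0.267 for the other 4 lists.

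Of 18 endothelial markers 6 fell under TNFa and 0 rose (0 and 13 adjusted over the list alone; adjusted p = 7.86e-08, or adjusted p = 0.119 with an estimated correlation). Of 20 coagulation genes 6 fell, including MMRN1, VWF and the anticoagulant receptor THBD (-0.51 ± 0.18; its probes at -1.10 and 0.062), and 0 rose (2 and 6 over all genes with centred values, 2 and 7 adjusted over the list alone). The list passed only after centring (adjusted p = 0.0389; adjusted p = 0.316 with an estimated correlation) and not without the iliac array (0.154), where its mean was -0.20 against -0.24 with all arrays. Of 35 cell cycle genes 4 fell, with TPX2 at -0.47 ± 0.25, CENPF at -0.43 and NUSAP1 at -0.36 ± 0.13, and 0 rose (0 and 4 adjusted over the list alone; adjusted p = 0.00389, or adjusted p = 0.267 with an estimated correlation). Of 12 MHC class II genes 1 rose, the protease CTSS (0.49 ± 0.11), which lost its call without the dermal or the colon array (deposited mean 0.35 and 0.34). The list had 1 and 0 members called over all genes with centred values and 2 and 0 adjusted over the list alone (adjusted p = 0.0193, or adjusted p = 0.267 with an estimated correlation, and 0.0857 without the iliac array, where the mean was 0.10 against 0.13). Cholesterol synthesis had 1 of 16 higher, HMGCS1 (0.61 ± 0.41), whose call was lost without any 1 of the aortic, iliac, dermal or colon arrays (deposited mean 0.55, 0.43, 0.33 and 0.56). Its list passed (3 and 0 adjusted over the list alone; adjusted p = 0.0183, or adjusted p = 0.316 with an estimated correlation). Leukocyte adhesion had 4 of 17 higher and 1 lower (6 and 4 adjusted over the list alone) and the IL-4/STAT6 list 3 of 26 higher and 2 lower (8 and 3 adjusted over the list alone), the latter with the eosinophil chemokine CCL11 at 1.66 ± 0.68 and the transglutaminase TGM2 at -0.998 ± 0.285. Both passed camera only as deposited (adjusted p = 0.00259 and 0.00561, with adjusted p = 0.179 and 0.385 with an estimated correlation; 0.137 after centring). With fry after centring both passed (adjusted p = 0.0039 and 0.00202). The remaining lists did not pass camera. Of these, extracellular matrix (higher, 0.0355) and housekeeping (lower, 0.0382) passed fry after centring. Extracellular matrix had 3 of 37 higher and 1 lower (5 and 3 adjusted over the list alone), with the metalloproteinases MMP3 (1.88 ± 0.47) and MMP10 (1.73 ± 0.51; its probes at 0.41 and 3.02). Angiogenesis had 2 of 25 higher and 3 lower (5 and 3 adjusted over the list alone), with a median of -0.040 and a mean of 0.017. Redox and metal response had 1 of 20 higher and 3 lower (6 and 4 adjusted over the list alone; median -0.019, mean 0.12), vascular tone 1 of 20 higher and 1 lower (1 and 1 adjusted over the list alone), complement 1 of 15 higher and 1 lower (1 and 1 adjusted over the list alone), and housekeeping 3 of 13 lower, with GAPDH at -0.39 ± 0.13 and its probe means from -1.05 to 0.019 (1 and 3 adjusted over the list alone).

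**Figure D2:**
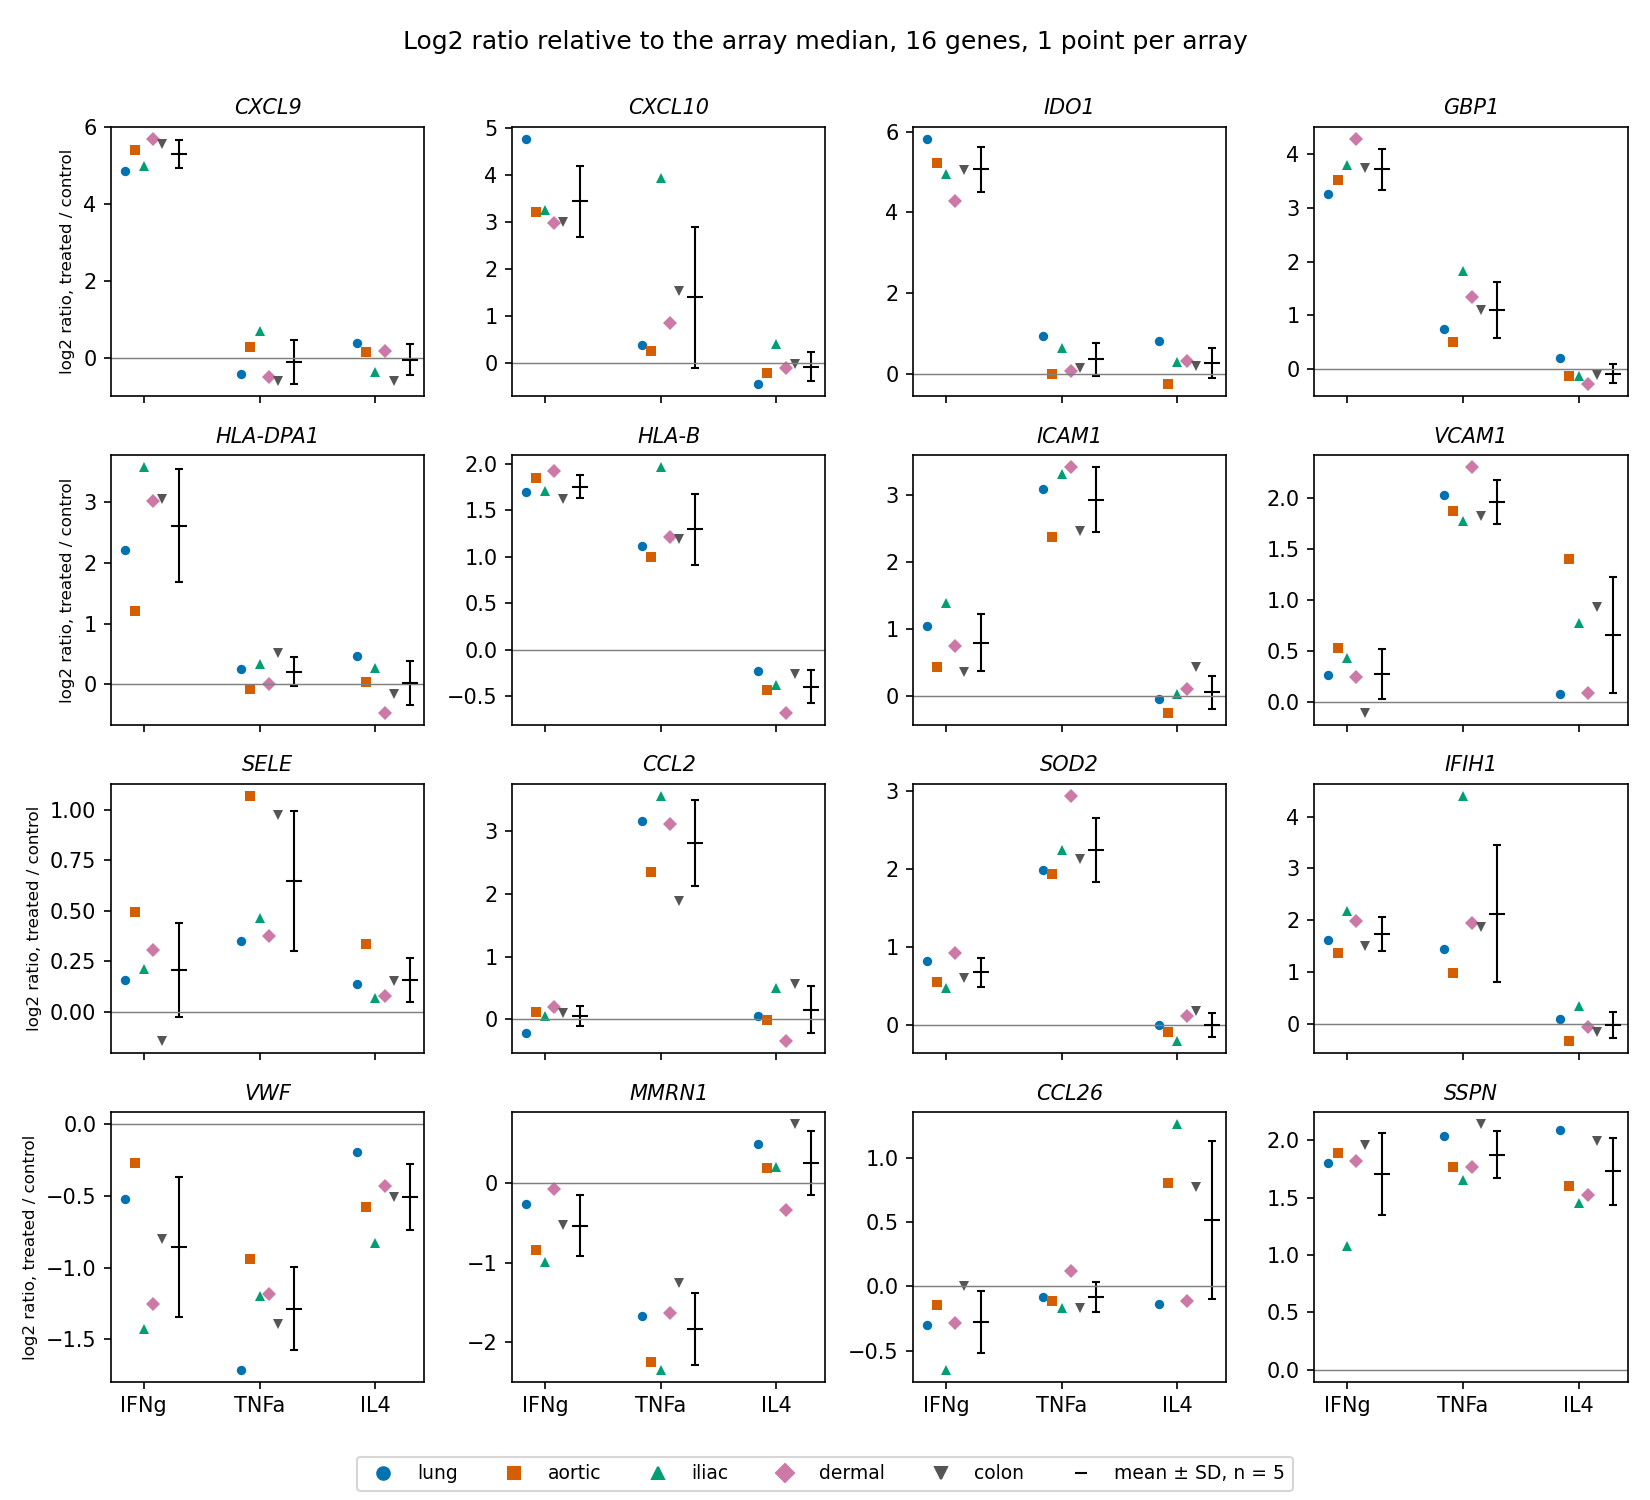
Log2 ratio relative to the array median for 16 genes, 1 point per array and cell source, with the mean ± SD of the 5 arrays of each cytokine. CXCL9 and IDO1 were high under IFNg, ICAM1, VCAM1 and CCL2 under TNFa, and SSPN lay between 1.07 and 2.14 on all 15 arrays.

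IL4 gave few calls, and most of them were shared with IFNg. In both deposited and centred values 12 genes rose and 17 fell. The highest was SSPN, a protein of the dystrophin complex (1.73 ± 0.29, 3.32-fold, n = 5), followed by CYP3A43 (0.65 ± 0.25), the helicase DHX33 (0.63 ± 0.13), the cytokine IL1A (0.62 ± 0.25) and the secreted Wnt antagonist SFRP1 (0.60 ± 0.08). Among the decreases, UQCR10 fell by 0.71 ± 0.26 (log2), the 14-3-3 protein YWHAQ by 0.69 ± 0.14 and FDPS, an enzyme of sterol synthesis, by 0.59 ± 0.05. SSPN lost its call without the colon array (deposited mean 1.55), and each of the other named genes without the aortic, the dermal or the colon array (FDPS at -0.67, -0.66 and -0.70). SSPN, CYP3A43, IL1A, UQCR10, YWHAQ and VWF belonged to 14 genes that had 1 sign on all 15 arrays and a mean at least 0.5 from the array median under each cytokine, SSPN being at 1.71 under IFNg and 1.87 under TNFa. The anchors did not pass: CCL26, eotaxin-3, was at 0.52 ± 0.62 (adjusted p = 0.161 after centring), and VCAM1 at 0.66 ± 0.57 (adjusted p = 0.0895), both with a wide spread between arrays. CCL26 was at -0.14 in lung, 0.80 in aortic, 1.26 in iliac, -0.12 in dermal and 0.77 in colon cells, and VCAM1 at 0.084, 1.40, 0.77, 0.095 and 0.93 in the same order. LOX, which crosslinks collagen, was at 0.83 ± 0.43 and passed as deposited (adjusted p = 0.0483) but not after centring (0.0527). KDR (-0.98 ± 0.56) and the 5'-nucleotidase NT5E (-0.94 ± 0.46) did likewise. In deposited values 579 genes were called, 28 higher and 551 lower, and after centring 30, 13 higher and 17 lower. Of these 13 and 17, 12 and 15 were called in the same direction under IFNg, and 7 and 13 under TNFa. Most of the centred calls were therefore not particular to IL4. With limma on deposited values 3525 genes had an unadjusted p under the threshold, and the adjusted count was 1 without aortic, 1418 without iliac, 2 without dermal and 0 without colon.

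None of the 19 pathway lists passed camera for IL4 after centring. With fry after centring, the IL-4/STAT6 and the cytokine lists (adjusted p = 0.0306 each) and MHC class II (0.0319) passed, all higher. As deposited, their fry adjusted p was 0.878, 0.488 and 0.601. The IL-4/STAT6 list had a median of 0.21 over 26 genes, of which 0 were called in both values and 12 were higher and 3 lower adjusted over the list alone (camera adjusted p = 0.116; as deposited 0.00138, and adjusted p = 0.98 with an estimated correlation). Cytokines and growth factors had 1 of 24 higher, IL1A (6 and 2 adjusted over the list alone), and cholesterol synthesis 1 of 16 lower, FDPS (0 and 3 adjusted over the list alone). The other lists had 0 members called in both values, and for IFN-gamma signalling, antiviral genes, chemokines, vascular tone, extracellular matrix, cell cycle and cell death the median, the mean and the test did not share 1 sign. Adjusted over the list alone, higher and lower members numbered 0 and 2 for IFN-gamma signalling, 1 and 0 for antiviral genes, 2 and 1 for MHC class I, 0 and 0 for MHC class II and 2 and 2 for NF-kB feedback, leukocyte adhesion, chemokines and extracellular matrix. They numbered 5 and 3 for coagulation, 0 and 2 for vascular tone and complement, 1 and 5 for angiogenesis and housekeeping, 0 and 0 for cell cycle, 1 and 0 for cell death and 0 and 3 for redox and metal response. Endothelial markers were lower as a list (adjusted p = 0.00174, or adjusted p = 0.337 with an estimated correlation), with 0 of 18 members called in both values and 1 and 6 adjusted over the list alone.

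Markers of other cell types gave few calls. Under IFNg 4 of 18 endothelial markers fell (2 and 4 adjusted over the list alone), and 1 of 6 lymphatic endothelial markers fell (0 and 1 adjusted over the list alone). Of 13 leukocyte, 9 fibroblast, 9 smooth muscle and pericyte and 7 epithelial markers 0 were called in both values under IFNg (0 and 0, 0 and 0, 1 and 0, and 2 and 0 adjusted over the list alone). Under TNFa 1 of 7 epithelial markers fell (0 and 1 adjusted over the list alone), and 0 lymphatic, leukocyte, fibroblast or smooth muscle markers were called in both values or adjusted over the list alone; the fibroblast list had a median of 0.020 and a mean of -0.074. Under IL4 0 markers of these lists were called in both values, with 2 and 0 fibroblast, 1 and 0 smooth muscle and 1 and 0 epithelial markers adjusted over the list alone and 0 lymphatic or leukocyte markers. The smallest camera adjusted p among these 5 lists after centring was 0.147, for epithelial markers under IL4. With fry after centring, epithelial markers passed under IL4 (adjusted p = 0.0326) and IFNg (0.0448), and smooth muscle and pericyte markers under IFNg (0.0373), all higher.

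**Figure D3:**
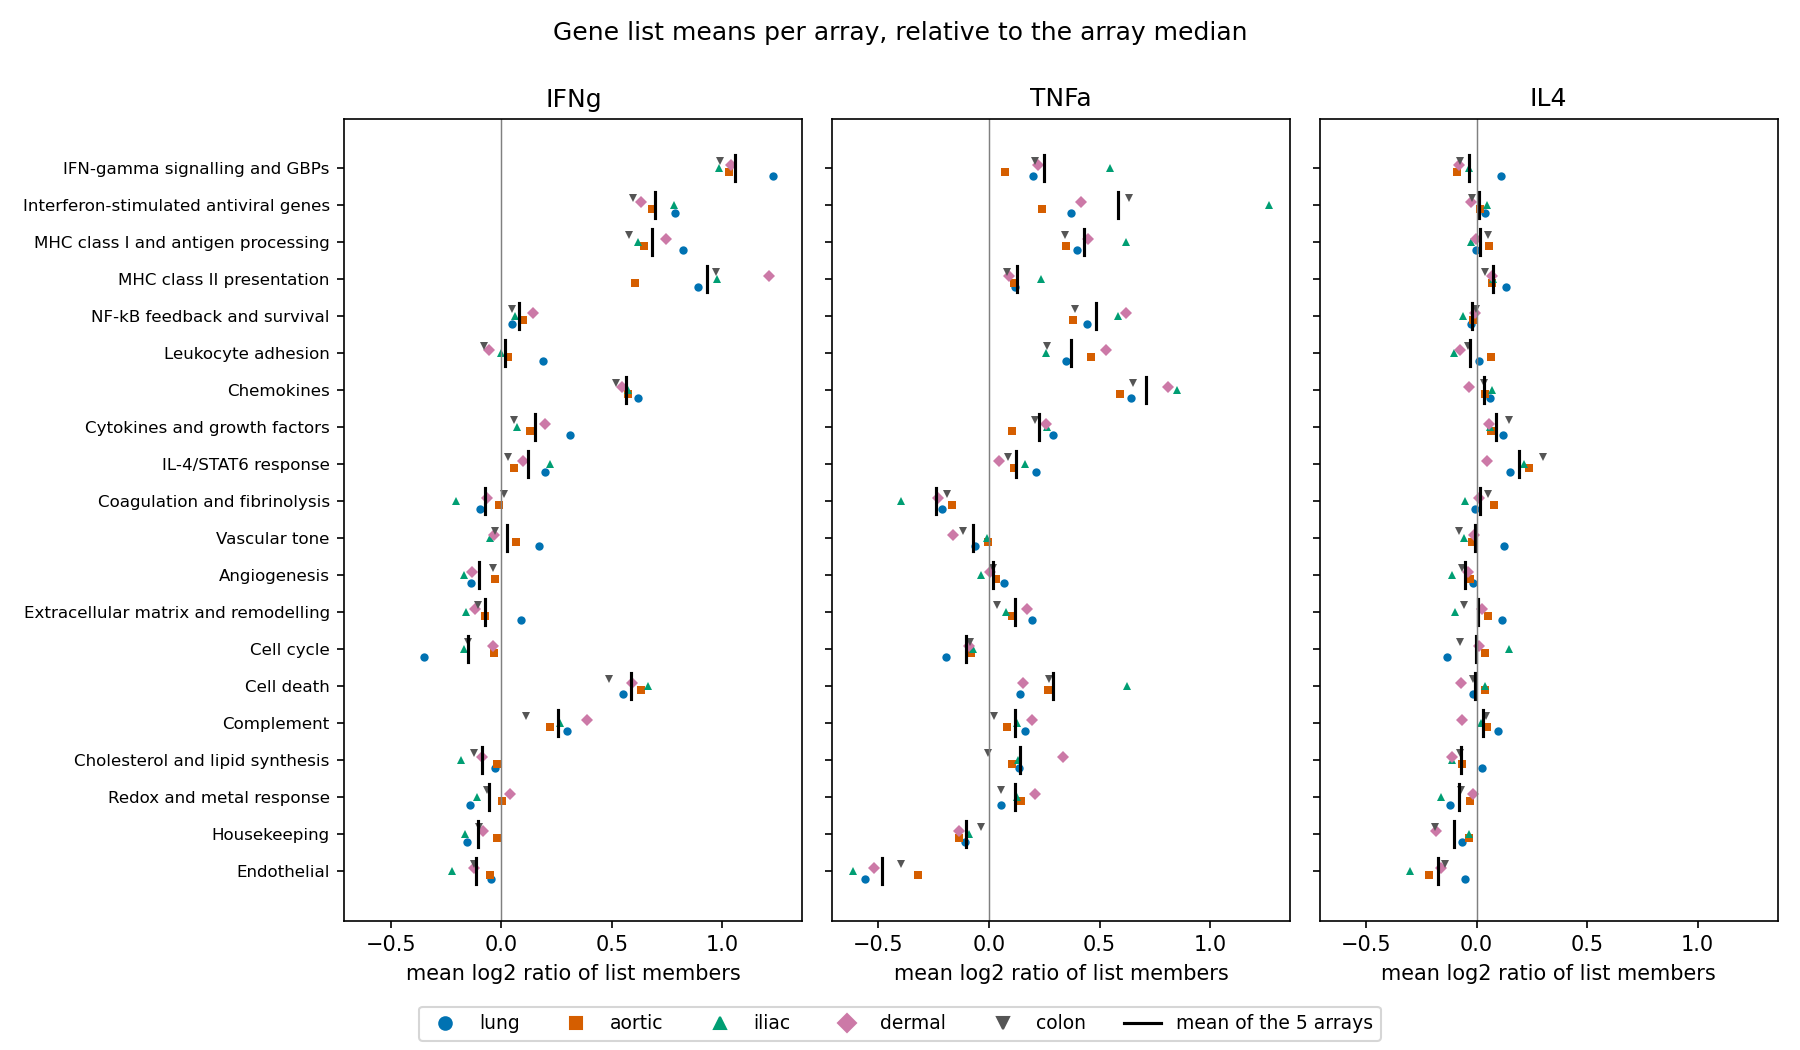
Mean log2 ratio of the members of each gene list, relative to the array median, 1 point per array and cell source and a bar for the mean of the 5 arrays of each cytokine. The 4 interferon and MHC lists lay highest under IFNg, and under TNFa the antiviral list reached 1.27 on the iliac array.

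TNFa and IFNg differed in 398 genes as deposited (280 higher and 118 lower under TNFa) and in 514 after centring (265 and 249), with 244 higher and 118 lower in both. CCL2 was 2.77 higher under TNFa on the centred log2 scale, MMP10 2.49, CXCL6 2.41, ICAM1 2.14, MMP3 2.07 and VCAM1 1.69. CXCL9 was lower under TNFa by the difference -5.40, IDO1 by -4.70, CXCL11 by -3.42, WARS1 by -3.09, GBP1 by -2.62 and HLA-DPA1 by -2.40. These 12 genes kept their calls without any 1 cell source. Of 27 NF-kB feedback genes 13 were higher under TNFa and 0 lower (adjusted p = 4.36e-13; adjusted p = 0.0133 with an estimated correlation). Of 29 chemokines 9 were higher and 2 lower (adjusted p = 3.03e-04; 0.0133), and of 17 adhesion genes 4 higher and 1 lower (adjusted p = 0.00129; 0.0462). Of 12 MHC class II genes 8 were lower under TNFa and 0 higher (adjusted p = 1.21e-17; adjusted p = 0.0133 with an estimated correlation), and of 22 IFN-gamma signalling genes 8 lower and 1 higher (adjusted p = 9.90e-11; 0.0462). The antiviral list did not pass (adjusted p = 0.067), with 3 of 35 lower under TNFa. The count was 229 without the lung arrays, 201 without aortic, 207 without dermal and 220 without colon, and 191 without the cell source block.

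TNFa and IL4 differed in 189 genes as deposited (137 higher and 52 lower under TNFa) and in 275 after centring (198 and 77), with 137 and 48 in both. ICAM1 was higher under TNFa by 2.88, CX3CL1 by 2.72, CCL2 by 2.66 and SOD2 by 2.24, while MMRN1 differed by -2.10, PALMD by -1.46 and LDB2 by -1.34. Of 27 NF-kB feedback genes 12 were higher under TNFa and 0 lower (adjusted p = 5.49e-26; adjusted p = 0.00145 with an estimated correlation), and of 29 chemokines 11 higher and 0 lower (adjusted p = 3.09e-13; 5.2e-04). Coagulation went the other way, with 3 of 20 genes lower under TNFa and 0 higher (camera adjusted p = 3.84e-05, or 0.0097 with an estimated correlation). IFNg and IL4 differed in 185 genes as deposited (103 higher and 82 lower under IFNg) and in 254 after centring (177 and 77), with 103 and 61 in both. CXCL9 was higher under IFNg by 5.34, CXCL11 by 4.81, IDO1 by 4.79, WARS1 by 3.89, GBP1 by 3.80 and SAMD9L by 2.65, while the peroxidasin PXDN differed by -0.88 and KRT7 by -0.79. Of 12 MHC class II genes 7 were higher under IFNg and 0 lower (adjusted p = 1.85e-24; adjusted p = 0.00497 with an estimated correlation), and of 22 cell death genes 10 higher and 0 lower (adjusted p = 2.58e-14; 0.00497). For TNFa against IL4 the count was 125 without the lung arrays, 120 without aortic, 95 without dermal, 89 without colon and 83 without the cell source block. For IFNg against IL4 it was 116, 78, 113, 102 and 86 in the same order. Without the IL4 lung array, whose labels name both lung and iliac cells, the counts were 119 and 138.

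The ratios under different cytokines correlated across genes. A gene-specific dye effect common to all 15 arrays would give such agreement too, and neither the simulated arrays nor the pairs from different sources remove it. After centring, 269 genes were called higher under both TNFa and IFNg, where independent lists of those sizes would share 40.6, and 299 lower, where they would share 41.3; 19 were called in opposite directions. The mean ratios of the 2 cytokines correlated across genes, which are not independent replicates, at r = 0.618. Simulated unchanged arrays that share their controls gave r = 0.45, which returns the correlation of 0.451 estimated from these arrays and put into the simulation. The same holds for the simulated r of the other pairs. Their 0 shared calls were to be expected from the setting, since no simulated gene was changed, so neither value is a test. The simulated covariance was 0.00446 against the observed 0.0361. Taken from different cell sources, which share no control in the labels, the correlation averaged 0.464 over 20 ways of dividing the sources. Each mean there rests on fewer arrays, which lowers r by noise alone. The covariance from different sources averaged 0.0319 for this pair, 0.0163 for TNFa and IL4 and 0.0226 for IFNg and IL4. TNFa and IL4 shared 7 higher and 13 lower genes (0.529 and 0.798 for independent lists; r = 0.576, simulated 0.447; covariance 0.0208, simulated 0.00444; 0.356 from different sources). IFNg and IL4 shared 12 of the 13 genes called higher under IL4 and 15 of the 17 called lower (1.08 and 1.25; r = 0.61, simulated 0.451; covariance 0.0268, simulated 0.00447; 0.411 from different sources). Between single arrays of 1 cytokine, the mean r across genes was 0.559 for IFNg, 0.458 for TNFa and 0.311 for IL4. Between arrays of 1 cell source and different cytokines it was 0.544 for IFNg and TNFa, 0.54 for TNFa and IL4 and 0.509 for IFNg and IL4, and between arrays that differ in both it was 0.334, 0.234 and 0.282.

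Cell sources differed in 4514 genes by the F test as deposited, in 3228 after centring and in 2153 with loess values, and 1777 genes were called in all of these. Departures of a source from the others were measured on centred values throughout, and only the set of called genes changed. Lung cells had the largest departure for 2362 of the 4514 genes called as deposited, 2217 of them higher, and 79.3% of the 2362 lay in the dimmer part of the genes. Among the 3228 genes called after centring the departure was largest in lung for 1885, 1340 of them higher, with 68.1% in the dimmer part. For genes called as deposited with the largest departure in aortic, iliac, dermal and colon cells the dimmer part held 83%, 61.5%, 62.2% and 77.3%. For genes called after centring, these shares were 44.7%, 48.9%, 49.5% and 81%. The largest F values belonged to PCLO, EVI2B, YBX2, FAM219B, PIWIL4, GRM5, CH25H and GPR18, of which PIWIL4, which acts in germline small RNA silencing, averaged 1.26 ± 0.14 on the 3 lung arrays and 0.12 to 0.28 elsewhere. CH25H, the cholesterol 25-hydroxylase, averaged 0.997 ± 0.242 in lung and -0.22 to 0.25 elsewhere. Most of these genes were dim: as log2 of the recovered whole numbers PIWIL4 was at 7.34 and CH25H at 7.82. The others ran from 5.36 (EVI2B) to 9.72 (YBX2), against a median of 9.86 for all probes. Ratios on the IFNg, TNFa and IL4 lung arrays rose as brightness fell (rank correlation -0.44, -0.26 and -0.31). The iliac arrays went the same way (-0.13, -0.18 and -0.28), and all aortic, dermal and colon arrays went the other way (0.024 to 0.23). Of 26 IL-4/STAT6 genes 10 differed between sources as deposited and 7 in all 3 kinds of values, and of 20 vascular tone genes 10 and 5. Of the markers of other cell types, 7 of 13 leukocyte markers differed as deposited and 5 in all 3 kinds of values, 4 and 2 of 9 fibroblast markers, and 4 and 3 of 9 smooth muscle and pericyte markers. Whether these shares exceed that of all genes, 4514 of 11936, was not tested. On the lung arrays of IFNg, TNFa and IL4 the centred mean was 0.36, 0.18 and 0.23 for leukocyte markers and 0.47, 0.19 and 0.32 for fibroblast markers. Because the 3 arrays of 1 source may share a control RNA, these differences can belong to the treated or to the control cells. The count was 1087 without the TNFa arrays, 1114 without the IL4 arrays, 4266 without the IFNg arrays and 3704 without the IL4 lung array alone. Between vessel cells (aortic and iliac) and organ cells (lung, dermal and colon) limma called 0 genes under each cytokine, as deposited and after centring, with 713 and 462 at an unadjusted p under the threshold for IFNg, 221 and 356 for TNFa and 109 and 233 for IL4; for IL4, 3 were called when genes with ratios near 0 were left out.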

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

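The tests of intensity trends, of a shared control or batch and of IFN-gamma in the TNFa iliac culture were chosen after the results were seen; the counts over other splits and the test of single probes were not.

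Among 228 sets of 5 gene values, 14 held an array far from the other 4, as did 8 of 75 sets of list means and 4 of 21 sets of array measures, where chance alone gives about 1 in 20. On the IFNg lung array CXCL10 was at 4.77 (others 2.98 to 3.24), BST2 at 2.68 (1.60 to 1.84) and TNFAIP2 at 1.23 (0.57 to 0.66). On the IFNg iliac array HHIP was at -1.94 (others -1.001 to -0.63). Under TNFa, the iliac array was highest for IFIH1 at 4.40 (others 0.99 to 1.94), HLA-B at 1.96 (0.99 to 1.21), APOL3 at 2.76 (0.66 to 1.19) and APOL1 at 2.73 (0.72 to 1.12). CTSS was lowest on the TNFa lung array at 0.29 (0.52 to 0.57) and EPHB4 on the TNFa dermal array at -0.94 (-0.51 to -0.37). Under IL4, IRF8 was at -0.47 (-0.18 to -0.089) and BCL2L1 at -0.72 (-0.40 to -0.28) on the iliac array, and LOX at 0.082 (0.81 to 1.11) and LAMC1 at -0.045 (-0.48 to -0.36) on the dermal array.

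Among list means, IFN-gamma signalling was highest on the lung array under IFNg at 1.23 (others 0.98 to 1.04) and under IL4 at 0.11 (-0.091 to -0.034). On the TNFa iliac array MHC class II was at 0.24 (0.081 to 0.12), coagulation at -0.40 (-0.23 to -0.17) and cell death at 0.62 (0.14 to 0.27), and on the TNFa lung array cell cycle was at -0.20 (-0.089 to -0.074). On the IFNg lung array leukocyte markers were at 0.36 (-0.00059 to 0.069) and smooth muscle and pericyte markers at 0.34 (0.054 to 0.14). Of the array measures, the IFNg lung array had 2512 probes at least 2-fold above its median (others 173 to 347) and a median denominator of 338 (787 to 959). The IFNg iliac array had 393 probes at least 2-fold below its median (109 to 188). The IL4 iliac array had an interquartile range of 0.422 (0.329 to 0.351).

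Antiviral genes stood out on the TNFa iliac array, where 31 of 35 members were above each of the other 4 TNFa arrays. IFN-gamma in that culture, or a swapped label, would bring MHC class II genes along. Their excess was 0.146 of the mean IFNg response (bootstrap 0.0444 to 0.286), against 1.23 for antiviral genes (0.95 to 1.57). This argues against a full IFNg response or a swapped label, but does not settle a weak or short exposure. The bootstrap resamples genes and does not measure the spread between cultures. On that array WARS1 was at 1.63 (others -0.33 to 0.27) and CXCL9 at 0.70 (others -0.61 to 0.29). IDO1 was at 0.64, below 0.92 on the TNFa lung array. On the IFNg iliac array these 3 genes were at 3.44, 4.98 and 4.96. CXCL10 was at 3.93 on the TNFa iliac array (other TNFa arrays 0.26 to 1.53), above 3.24 on the IFNg iliac array. CXCL11 was at 2.97 (0.52 to 1.24) and GBP1 at 1.82 (0.50 to 1.34), against 5.26 and 3.80 on the IFNg iliac array. An intensity trend is argued against by the loess values, in which the antiviral mean was 1.27 on the TNFa iliac array and at most 0.63 on the other TNFa arrays. A different response of iliac cells may be the reason, but with 1 iliac array for TNFa it was not tested.

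Cell sources differed in 4514 genes by a test of the difference itself, and arrays of 1 source resembled each other across cytokines. Of 100 permutations of the sources within cytokines, the real one included, 1 gave as many genes and the highest of the others gave 1812, so a chance arrangement can be excluded for the deposited values. Under IFNg, TNFa and IL4 the array medians were alike in aortic (-0.33, -0.27 and -0.24) and lung cells (0.029, -0.0075 and -0.024), but not in iliac cells (-0.26, -0.040 and 0.035). An offset of whole arrays shared by a source can therefore add to the 4514, and centred values were not permuted. After loess the gap in r between arrays of the same and of different sources was at least 0.0788 (iliac; 0.395 for lung), which argues against an intensity trend as the whole cause. Arrays of 1 source correlated at 0.451 within the fit of deposited values. Because each source may have shared a control RNA or a hybridisation batch, that explanation and a response that differs by cell type cannot be told apart. The cause of the difference stays open.

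Other splits of the arrays were also counted for the differences between cytokines. Of 100 splits of 10 arrays into 5 and 5, the real one included, 1 gave as many genes in each comparison. The real split gave 398 for TNFa against IFNg (highest other 3), 189 for TNFa against IL4 (1) and 185 for IFNg against IL4 (2). Only splits that part all 5 cell sources keep the pairing of the arrays. Among these 16 splits, 1 gave as many genes in each comparison, and the highest other was 3, 0 and 0. A share of 1 in 16 is the smallest possible there, which is too coarse to exclude a chance arrangement at the threshold used. A split that mixes the cytokines also leaves their difference in the residual spread, so few calls were likely from the outset.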

How the results depend on the processing

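The loess values and the centred values without 1 array were chosen after seeing the data; the other alternatives were planned. For genes changed by IFNg, 3859 in the deposited values, the count was 1877 centred, 2406 centred and scaled, 9005 with every probe by itself, 2419 with an absolute log2 of at least 0.5 on 1 array, 30 against a minimum log2 of 0.5, 2379 with loess and 2074 for the brighter genes with loess. Leaving out 1 array gave 862 (dermal) to 7733 (lung). In the same order the TNFa count of 1870 became 1046, 1097, 3103, 1087, 13, 1144 and 1028, and 429 (dermal) to 2580 (lung) with 1 array left out, and 552 centred without iliac. The IL4 count of 579 became 30, 182, 1, 213, 0 and 355 up to the loess values, 1569 with all 15 arrays in 1 fit, 1295 with a random cell source block, 42 centred without lung, and 0 (colon) to 1418 (iliac) with 1 array left out. The minimum size of change used limma's treat; its 0 for IL4 stands beside 3525 genes at an unadjusted p under the threshold. The cause was not tested.

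Between cytokines, every probe by itself gave 656 for TNFa against IFNg (398), 287 for TNFa against IL4 (189) and 287 for IFNg against IL4 (185), and the fit without the cell source block gave 191, 83 and 86. The 10 arrays of a pair alone gave 196 for TNFa against IFNg and 113 for IFNg against IL4, with fewer arrays. Leaving out 1 cell source gave 201 to 411, 89 to 175 and 78 to 193. For TNFa against IL4, scaling gave 330 and leaving out the IL4 lung array 119. For cell sources (4514), every probe by itself gave 9585, loess 2153, and the fits without the TNFa and the IL4 arrays 1087 and 1114. Between vessel and organ cells under IL4, 3 genes were called with the filter on small ratios. The cause was not tested.

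Of 276 named gene values, 208 kept their side of the threshold and direction after centring, 67 lost the threshold and 1 gained it; with 1 array or cell source left out 1012 kept it, 364 lost it and 4 gained it. As deposited, single probes reversed the sign for GBP3 (-0.30 under IFNg, -0.29 under TNFa, 0.011 for TNFa minus IFNg, -0.30 for IFNg minus IL4), LGALS3BP (-0.31 under IFNg), ANGPT2 (0.22 under IFNg), NQO1 (0.040 under IFNg), TAPBP (-0.30 under TNFa), PTGS2 (-0.24 under TNFa), SOD2 (-0.031 for TNFa minus IL4) and KRT7 (0.018 for IFNg minus IL4); the cause was not tested. After centring that GBP3 probe was at -0.12 under IFNg and -0.17 under TNFa, so its TNFa minus IFNg difference was not reversed. Of 75 camera list tests, 65 kept their side and direction after centring. With an estimated correlation, all 24 lists that had passed as deposited lost the threshold, and the 51 that kept their side had not passed. The smallest camera adjusted p there was 0.0755, for endothelial markers under TNFa. Mean correlations between single arrays stayed positive with Spearman's rank, but IFNg arrays of different sources (0.467) then lay below the pairs of 1 source with TNFa or IL4 (0.553 and 0.556). Correlations of mean ratios were not ranked. No value was missing, so the alternative treatment of missing values was not run. Signal over background was not analysed here, since the table holds ratios.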

Other observations

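The test of the single probe was chosen before its result was seen, and the test of an intensity trend after.

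Some ratios were alike under all 3 cytokines: with 1 sign on all 15 arrays and a mean at least 0.5 from the array median under each cytokine there were 74 probes, 31 higher and 43 lower, and 14 genes, 3 higher and 11 lower. SSPN averaged 1.77 ± 0.28 over the 15 arrays, CYP3A43 0.66 and IL1A 0.58, while VWF averaged -0.88, APLN -0.90, RPS3A -0.87 and UQCR10 -0.82. If the single probe or its dye were the reason, other probes of the same gene would keep little of the ratio: they kept a median share of 0.191, against 0.504 for genes that differ between TNFa and IFNg, a difference of -0.313 (bootstrap -0.436 to -0.142). The dye or sequence of a probe may contribute to part of these ratios, but SSPN, CYP3A43, IL1A, RPS3A and UQCR10 have 1 probe each, so the test does not reach them, and the 2 probes of VWF (-0.87 and -0.86 under IFNg) and of APLN (-0.66 and -0.97) were alike, which argues against an effect of a single probe there. After loess 82.4% of the probes stayed at least 0.5 from 0, which argues against an intensity trend.

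The labels of the IL4 lung array name both lung and iliac cells in its treated channel. Across genes it correlated at 0.717 with the IFNg lung and 0.701 with the TNFa lung array, and at 0.317, 0.203 and 0.194 with the iliac arrays of IFNg, TNFa and IL4. Whether the control or the treated cells carry this resemblance was not tested.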
